A study of Arabidopsis thaliana with 18 samples.

How the data were processed

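Transcript levels were measured on Affymetrix ATH1 arrays, which carry probe sets for most annotated genes of Arabidopsis thaliana. Whole rosettes of Col-0 plants aged 20 days, grown in continuous light, were exposed for 1 h to sound of a single frequency at 80 dB in a soundproof chamber, and the control plants stood in silence for as long. Tissue was taken right after the exposure. There were 6 groups (control, 250, 500, 1000, 2000 and 3000 Hz) of 3 biological replicates, 18 arrays in all, with biotin-labelled cRNA made from total RNA.

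The deposited values are log2 signals per probe set, 1 column per array. Affymetrix Expression Console 1.1, RMA and MAS5 were used per the submitters' processing notes, which do not say which of these made the deposited column. The medians of the arrays lay between 6.51 and 6.63 on the log2 scale, so no further scaling was applied for the results given. Of 22810 probe sets, 64 Affymetrix control probe sets were set aside and 22746 were tested.

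Genes were matched to the probe sets through the identifiers in the platform's table and the RefSeq annotation. A single gene was found for 13523 probe sets, several genes for 493, and none that could be named for 8730, which were tested but not named. These 8730 include the probe sets of TCH1, TCH2, TCH3 and TCH4, the touch genes chosen for reporting whatever their values, so they are not reported here. No genome build was used, so genes are given by symbol and locus without coordinates.

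The comparisons, tests, alternatives, 20 gene lists and the rule for named genes were chosen before the data were examined. All 6 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). Each frequency was compared with the control, as was the average of the 5 frequencies. Differences among the frequencies were tested with a moderated F test over the 5 sound groups, and a trend with a slope on log2 frequency. P values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets, the limma tests were two-sided, and an adjusted p under 0.05 counted as a change. Errors are standard errors of the fit unless SD is given, and n is 3 arrays per group. The number of arrays limits the precision of every value. Direct comparisons of pairs of frequencies were added after the data had been seen.

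The rule named, for each frequency, the 6 largest rises and 6 largest falls among probe sets that passed, had 1 gene and had all 3 sound arrays beyond all 3 control arrays. It also named from each list the passing member with the largest change. Where none passed, the 3 higher and 3 lower genes with the smallest p are given as values. For the average, the 10 largest rises and falls were named, and among the frequencies the 6 genes with the smallest adjusted p. Other list members that passed are named as examples, chosen after their values were seen.

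Few members of the 20 lists could be named on the array: 50 of 363 genes, with at least 3 members in 8 lists, 1 or 2 in 11 and none in the list of floral markers. Therefore 16 further lists, with 326 of 393 genes measured, were added after the annotation had been seen and before any list was tested. The 24 lists with at least 3 measured members covered touch and mechanical response, jasmonate synthesis and response, cold (CBF) response, reactive oxygen, cell wall loosening, heat shock, early auxin response and root markers. The added ones covered rapid stress response, calmodulin-like proteins, XTH and expansin genes, cytosolic ribosomal proteins, chaperones, clock-associated genes, nuclear photosynthesis genes, plastid-encoded genes, UGT glycosyltransferases, glutathione transferases, SWEET transporters, cold-regulated and dehydrin genes, the unfolded protein response, IAA and GH3 genes, pollen markers and root and root hair markers. Each list was tested at each frequency with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The p values were adjusted over the 120 tests, and separately over the 24 tests of the average. The camera test compares a list with the other genes, whereas fry tests whether a list's genes move on balance in 1 direction. Whether list members differed among the frequencies more often than other genes was tested with Fisher's exact test (one-sided) against 13286 genes, which takes genes as independent.

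Log2 changes of pairs of frequencies were correlated across probe sets, which are not independent replicates, and set against 20 simulations of unchanged groups that share the control arrays. RNA quality was read from the 3' minus 5' signals of the actin and GAPDH control probe sets, and labelling from the 24 poly-A spike control probe sets. The fit was tested on simulated data, in which 50 probe sets for each size had been changed at 500 Hz. It recovered 64% of changes of 0.5 on the log2 scale, 86% of changes of 1 and 96% of changes of 1.5 or 2, with 6 unchanged probe sets called. The simulated noise was independent between probe sets and had the same SD in all groups. The real controls varied more than the sound groups, so these shares do not carry over to comparisons with them.

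Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of probe sets, 2 other variance models, array weights, replicate number as a block, only the 6 arrays compared, a test without shared variance, and each array left out in turn. Replicate numbers did not pair the arrays, since 0 of 15 pairs of groups had all 3 residual correlations above 0.1 (range -0.32 to 0.35), so the fit has no replicate term. Alternatives that separate the arrays by poly-A spike signal were added after the data had been seen. A pseudocount was not needed for log2 values. Figures were drawn with matplotlib.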

Results

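Rosette transcripts were measured after 1 h of sound at 80 dB at 250, 500, 1000, 2000 or 3000 Hz and after 1 h of silence, with 3 arrays in each of the 6 groups. The comparisons ask which transcripts differ from silence at each frequency, and which differ between frequencies. All 5 frequencies share the same 3 control arrays.

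The control arrays differed from each other more than the arrays of any sound group did. EXO (AT4G08950), a cell expansion gene, had log2 signals of 8.93, 12.72 and 8.75 on control replicates 1, 2 and 3, against 12.36 to 13.25 on the 15 sound arrays. AT2G15020 had 8.01, 3.9 and 7.87 on the controls and 3.88 to 4.70 on the sound arrays, so control replicate 2 lay with the sound arrays for both genes. Control replicates 1 and 2 differed by at least 2-fold at 1308 probe sets, whereas control replicate 2 and 1000 Hz replicate 3 did so at 140. The mean variance was 0.103 in the control group and 0.027 to 0.046 in the sound groups. The fit shares the variance over all 6 groups. Where the controls spread widely, as for EXO and AT2G15020, its errors and p values against control are therefore too small. PYK10 (AT3G09260), an abundant root beta-glucosidase, had 8.67 on control replicate 1 and 5.38 and 5.82 on replicates 2 and 3. The actin 3' minus 5' signal, a sign of RNA quality, was 1.94 ± 0.017 (SD, n = 3) in the controls and between 1.61 ± 0.055 at 3000 Hz and 2.06 ± 0.29 at 500 Hz in the sound groups.

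The arrays fell into 2 sets by the poly-A spike controls, which are bacterial transcripts added before labelling. Their mean log2 signal was 5.37 to 5.59 on the 12 control, 250, 500 and 1000 Hz arrays and 5.99 to 6.51 on the 6 arrays of 2000 and 3000 Hz. No control array lay in the higher set, so for 2000 and 3000 Hz against control the labelling set and the sound cannot be told apart.

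**Figure D1:**
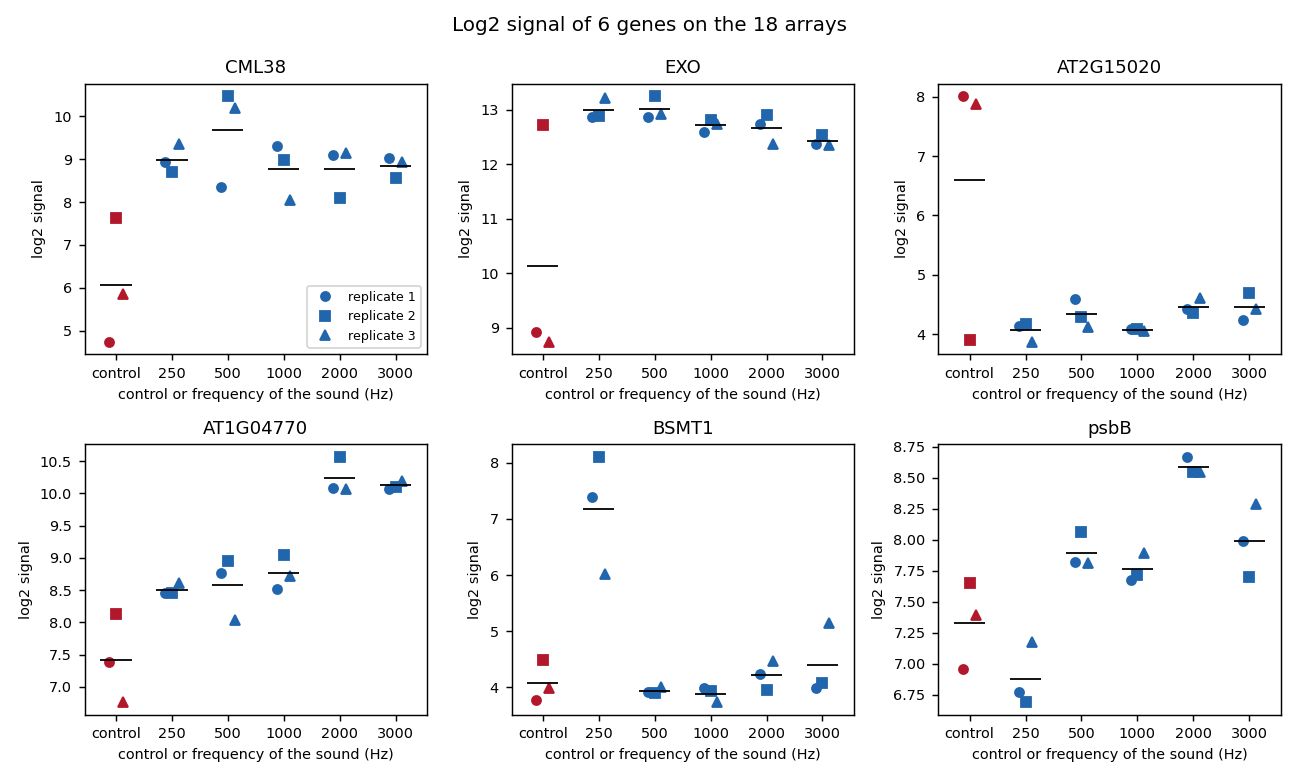
Log2 signal (vertical axes) of CML38, EXO, AT2G15020, AT1G04770, BSMT1 and psbB on each array, by control or frequency in Hz (horizontal axes). Points are arrays, marked by replicate, with controls in red and sound in blue, and bars are group means of 3 arrays. For EXO, control replicate 2 lies at 12.72 and the other controls at 8.93 and 8.75.

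At 250 Hz, BSMT1 (AT3G11480), which makes methyl salicylate and methyl benzoate, rose by 3.09 ± 0.39 on the log2 scale (8.5-fold, adjusted p = 0.0056, n = 3). Its signals were 7.39, 8.11 and 6.01 at 250 Hz, 3.78 to 4.49 in the controls, and 3.73 to 5.14 on the 12 arrays of the other frequencies. Because the fit shares the variance over the groups, it understates this spread at 250 Hz, and the error and p values of BSMT1 are too small. BSMT1 also differed among the 5 frequencies (adjusted p = 0.00196). The proline dehydrogenase gene AT5G38710 rose by 1.39 ± 0.18, AT4G23870 by 1.39 ± 0.21, AT3G51450 by 0.95 ± 0.15 and the histone H2B gene AT2G37470 by 0.87 ± 0.10. AT3G30460 fell by 0.98 on the log2 scale (SE 0.16). In all, 8 probe sets were higher and 2 lower, with 3601 at an unadjusted p under 0.05.

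Camera at the preset correlation called touch and stress genes higher as groups at 250 Hz, although 0 of their members passed alone in limma's test over all genes. The 27 rapid stress response genes had a median change of 0.70, with 26 of 27 positive and 14 higher when adjusted over the list alone (camera adjusted p = 1.51e-10; adjusted p = 0.676 with an estimated correlation). Among 7 touch and mechanical response genes the median was 0.60, with 5 higher when adjusted over the list alone (adjusted p = 0.000224; adjusted p = 0.676 with an estimated correlation). The 6 cold-regulated and dehydrin genes had a median of 1.00 (adjusted p = 0.000237), the 4 cold (CBF) response genes 0.81 (adjusted p = 0.00733) and the 8 calmodulin-like genes 0.33 (adjusted p = 0.0320), with 5, 3 and 3 members higher when adjusted over the list alone. All 3 had adjusted p = 0.676 with an estimated correlation. The 69 plastid-encoded genes lay lower, with a median of -0.33, 1 positive member and 11 lower when adjusted over the list alone (adjusted p = 4.14e-13; adjusted p = 0.676 with an estimated correlation). The calmodulin-like call ended without control replicate 1 (median 0.106, adjusted p = 0.439) or 250 Hz replicate 2, with a median of 0.522 without control replicate 3, and the cold (CBF) call without 250 Hz replicate 3 (adjusted p = 0.0534).

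The count of 10 at 250 Hz became 3 without 250 Hz replicate 1, 69 without 250 Hz replicate 3 and 2175 without control replicate 2. BSMT1, AT4G23870, AT3G51450 and AT3G30460 missed the threshold without 250 Hz replicate 1, AT4G23870 and AT3G30460 also without control replicate 1 or 3, and AT3G51450 also without control replicate 3 or 250 Hz replicate 2, whereas AT5G38710 and AT2G37470 passed with any of the 6 arrays left out.

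At 500 Hz, AT2G20670 rose by 3.99 ± 0.75 on the log2 scale (15.8-fold, adjusted p = 0.0109, n = 3), the calmodulin-like gene CML38 (AT1G76650) by 3.60 ± 0.61 (12.1-fold, adjusted p = 0.00962) and AT3G62950 by 3.28 ± 0.57. EXO rose by 2.88 ± 0.67, AT1G02660 by 2.76 ± 0.61 and AT2G44500 by 2.69 ± 0.56. The largest falls were those of the cellulase-family gene GH9C2 (AT1G64390), by 1.98 on the log2 scale (SE 0.51), AT1G60590, by 1.93 (SE 0.52), and AT1G52770, by 1.91 (SE 0.36). Without control replicate 1 the changes of GH9C2 and AT1G60590 were -1.208 and -1.218. AT2G44940 dropped by 1.84 (SE 0.37), the trichome regulator GIS (AT3G58070) by 1.64 (SE 0.32) and AT1G48330 by 1.63 (SE 0.28). In all, 941 probe sets were higher and 1085 lower, of which 394 and 129 changed at least 2-fold. After centring each array on its median, 1196 were higher and 800 lower.

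Of 27 rapid stress response genes, 11 rose at 500 Hz, or 18 when adjusted over the list alone, with all 27 positive and a median of 1.24 (camera adjusted p = 9.70e-12; adjusted p = 0.676 with an estimated correlation). CML38 and EXO led them, followed by AT4G29780 at 2.34 ± 0.53 and the immune transcription factor WRKY22 at 2.24 ± 0.43. Both EXO and CML38 are also among the 7 touch genes, of which 2 rose, or 3 when adjusted over the list alone (median 1.54, adjusted p = 0.00797; adjusted p = 0.676 with an estimated correlation). CML38 was the 1 of 8 calmodulin-like genes that rose, also when adjusted over the list alone (median 0.35, adjusted p = 0.0448; adjusted p = 0.676 with an estimated correlation). Among 27 XTH and expansin genes, which act on the cell wall, 5 rose and 1 fell, or 8 and 2 when adjusted over the list alone (adjusted p = 0.344). XTH18 rose by 2.61 ± 0.65, XTH33 by 2.29 ± 0.46, EXLA1 by 2.06 ± 0.49 and XTH19 by 1.84 ± 0.51, while EXPA4 fell by 1.14 on the log2 scale (SE 0.23). EXLA1 and EXPA4 are also the 2 of 4 cell wall loosening genes that changed, with 2 higher and 2 lower when adjusted over the list alone (adjusted p = 0.977).

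The cytokinin response regulators RR16 and ARR15 both fell at 500 Hz, by 1.57 (SE 0.26) and 0.94 (SE 0.24) on the log2 scale. Among 47 UGT glycosyltransferases 1 rose and 4 fell, UGT71B1 by 1.49 (SE 0.30), or 2 and 4 when adjusted over the list alone (adjusted p = 0.481). Of 14 unfolded protein response genes 3 rose and 2 fell, or 4 and 2 when adjusted over the list alone (adjusted p = 0.627). Its regulator BZIP60 rose by 0.98 ± 0.23. OPCL1, of jasmonate synthesis, rose by 0.66 ± 0.18 as the 1 of 3 jasmonate genes, also when adjusted over the list alone (adjusted p = 0.178). IAA33 rose by 0.27 ± 0.06 as the 1 of 12 IAA and GH3 genes, or 2 when adjusted over the list alone (adjusted p = 0.230). The 26 cytosolic ribosomal protein genes had a median of -0.20 with 0 passing in limma, also when adjusted over the list alone (camera adjusted p = 0.00451; adjusted p = 0.919 with an estimated correlation).

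The count of 2026 at 500 Hz became 2 without 500 Hz replicate 2, 581 without 500 Hz replicate 3, and 182, 4075 and 1285 without control replicates 1, 2 and 3, while the 12 arrays of the lower spike set gave 709. Of the 19 named genes, 0 passed in limma without 500 Hz replicate 2, and 10, 4 and 14 passed without 500 Hz replicate 3 and control replicates 1 and 3. The touch call ended without 500 Hz replicate 2, where the median of 1.54 became 0.467 (adjusted p = 0.0548). The calmodulin-like call ended without that array or control replicate 1 (medians 0.159 and 0.143, highest adjusted p = 0.318), and the ribosomal call without control replicate 1 (median -0.042, adjusted p = 0.900).

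At 1000 Hz, 0 probe sets passed in limma, with 3516 at an unadjusted p under 0.05 and a smallest adjusted p of 0.128. The same 0 came from the 6 arrays alone (1921 unadjusted) and from a test without shared variance (1440 unadjusted). The log2 differences with the smallest p were 1.01 ± 0.18 for AT5G11000, 0.58 ± 0.11 for AT5G41550, 1.83 ± 0.36 for AT1G70740, -0.70 ± 0.13 for AT2G06000, -0.53 ± 0.10 for the transcription factor gene bHLH104 and -0.70 ± 0.13 for AT4G38810. CML38 stood at 2.70 ± 0.61 (adjusted p = 0.128) and EXO at 2.58 ± 0.67 (adjusted p = 0.132). The 27 rapid stress genes had a median of 0.65, with 25 positive and 8 higher when adjusted over the list alone (camera adjusted p = 9.62e-08; adjusted p = 0.676 with an estimated correlation). Medians were 0.69 for the 6 cold-regulated and dehydrin genes, with 1 higher when adjusted over the list alone (adjusted p = 0.0320; adjusted p = 0.676 with an estimated correlation), and 0.12 for the 69 plastid-encoded genes, with 1 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0115; adjusted p = 0.949 with an estimated correlation).

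Without control replicate 2, 2177 probe sets passed at 1000 Hz, among them all 6 named genes, and 5 passed without control replicate 3. The cold-regulated call ended without control replicate 1 (median 0.363) or 1000 Hz replicate 3 (highest adjusted p = 0.173) and the plastid call without control replicate 1 (adjusted p = 0.246). The rapid stress median was 1.007 without control replicate 3, and the plastid median 0.182 without control replicate 2.

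At 2000 Hz, AT1G04770, known from plants short of sulfur, rose by 2.82 ± 0.28 on the log2 scale (7.05-fold, adjusted p = 0.000678, n = 3). AT2G20670 rose by 3.71 ± 0.75, AT3G62950 by 2.86 ± 0.57, CML38 by 2.71 ± 0.61, AT3G07350 by 2.58 ± 0.40 and AT4G37240 by 2.38 ± 0.50. Falls were smaller, led by AT4G16447, by 1.31 (SE 0.27), AT2G14900, by 1.27 (SE 0.28), and AT1G48330, by 1.26 (SE 0.28). MSRB9, a methionine sulfoxide reductase, dropped by 1.22 (SE 0.28), AT2G38870 by 1.2 (SE 0.27) and AT3G05600 by 1.19 (SE 0.30). In all, 369 probe sets were higher and 288 lower, of which 120 and 35 changed at least 2-fold.

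Plastid-encoded transcripts rose as a group at 2000 Hz, on arrays whose spike controls also stood 0.78 higher and whose actin 3' minus 5' signal was 1.75 ± 0.086 (SD, n = 3). Of 69 genes 20 rose, or 34 when adjusted over the list alone, with 66 positive and a median of 0.31 (camera adjusted p = 2.15e-21; adjusted p = 0.676 with an estimated correlation). They include genes of photosystem II, psbB at 1.26 ± 0.18 and psbD at 1.18 ± 0.19, and of photosystem I, psaA at 1.06 ± 0.17. The 21 nuclear photosynthesis genes had a median of 0.17 with 0 passing in limma, also when adjusted over the list alone, and 17 positive (camera adjusted p = 0.000241; adjusted p = 0.676 with an estimated correlation). Of the rapid stress genes 2 rose, CML38 and AT5G52050 at 1.56 ± 0.33, or 5 when adjusted over the list alone (median 0.26, adjusted p = 0.00398; adjusted p = 0.809 with an estimated correlation). CML38 was also the 1 of 7 touch genes, and of 8 calmodulin-like genes, that rose, or 3 and 1 when adjusted over the list alone (adjusted p = 0.186 and 0.896).

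LTI30 (AT3G50970), a dehydrin gene, rose at 2000 Hz by 1.49 ± 0.36 as the 1 of 4 cold (CBF) genes (median 0.57, adjusted p = 0.0336) and of 6 cold-regulated and dehydrin genes (median 0.78, adjusted p = 0.0115), each also 1 when adjusted over the list alone. Both lists had adjusted p = 0.676 with an estimated correlation. ARR15 fell by 1.12 on the log2 scale (SE 0.24), the ER chaperone gene ATERDJ2B rose by 0.57 ± 0.12 and GH3.9 by 0.90 ± 0.20, or 0.587 without 2000 Hz replicate 1. UGT88A1 rose by 0.87 ± 0.18, in a list where 1 of 47 rose and 1 fell, or 2 and 1 when adjusted over the list alone (adjusted p = 0.378). The 26 cytosolic ribosomal protein genes had a median of -0.20 with 0 passing in limma, also when adjusted over the list alone (camera adjusted p = 0.00451; adjusted p = 0.919 with an estimated correlation).

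The count of 657 at 2000 Hz became 48 without 2000 Hz replicate 1, 111 without 2000 Hz replicate 3, 2576 without control replicate 2 and 104 without control replicate 3. AT1G04770, AT3G07350 and psbB passed with any of the 6 arrays left out, the other 15 named genes did not. Calls ended without control replicate 1 or 2000 Hz replicate 3 for the rapid stress (highest adjusted p = 0.472), ribosomal (0.940), cold-regulated (0.227) and cold (CBF) lists (0.351), the last also without control replicate 2. Without control replicate 1 the rapid stress median of 0.26 became 0.043, the cold-regulated median 0.377 and the ribosomal median -0.009, where camera's direction turned. Without 2000 Hz replicate 3 they were 0.102, 0.466 and -0.108, and the cold (CBF) median was 0.250. Higher values came without control replicate 2 for the rapid stress (0.403) and cold-regulated genes (1.169) and without 2000 Hz replicate 2 for the cold (CBF) genes (0.872), and the ribosomal median was -0.301 without control replicate 3 and -0.317 without 2000 Hz replicate 2.

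At 3000 Hz, AT1G04770 rose by 2.70 ± 0.28 on the log2 scale (6.5-fold, adjusted p = 0.000603, n = 3), AT2G20670 by 3.23 ± 0.75 and AT3G62950 by 3.1 ± 0.57. CML38 rose by 2.76 ± 0.61, AT2G41640 by 2.40 ± 0.53 and AT3G07350 by 2.27 ± 0.40. AT4G19430 fell by 1.59 on the log2 scale (SE 0.37), AT1G63840 by 1.45 (SE 0.36), AT5G17600 by 1.45 (SE 0.36; 0.957 without control replicate 1), AT1G78170 by 1.37 (SE 0.29), AT1G79160 by 1.31 (SE 0.22) and AT2G25590 by 1.31 (SE 0.19). In all, 647 probe sets were higher and 855 lower, of which 113 and 69 changed at least 2-fold. After centring each array on its median, 842 were higher and 685 lower.

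Cytosolic ribosomal protein genes rose as a group at 3000 Hz, where 9 of 26 rose, or 22 when adjusted over the list alone, with all 26 positive and a median of 0.42 (camera adjusted p = 2.78e-12; adjusted p = 0.676 with an estimated correlation). The poly-A spike mean of these arrays was 6.185 against 5.457 in the controls, and the actin 3' minus 5' signal 1.61 ± 0.055 against 1.94 ± 0.017 (SD, n = 3). AT3G16780 rose by 0.83 ± 0.20 and AT5G07090 by 0.64 ± 0.16. Control replicate 1 lay near the 3000 Hz arrays for these genes, 0.36 above the gene means, against 0.40 to 0.46 at 3000 Hz. PYK10, the root gene, had a mean of 7.07 ± 0.07 (SD, n = 3) at 3000 Hz and 4.83 ± 0.64 at 2000 Hz (adjusted p = 0.119 for the difference). Of 69 plastid-encoded genes 12 rose and 2 fell, or 17 and 2 when adjusted over the list alone (median 0.23, adjusted p = 1.28e-05; adjusted p = 0.803 with an estimated correlation), with psaA at 0.95 ± 0.17 and petL at -0.65 ± 0.13. Of the rapid stress genes 3 rose, or 10 when adjusted over the list alone (median 0.59, adjusted p = 2.85e-05; adjusted p = 0.676 with an estimated correlation), namely CML38, AT5G52050 and the ubiquitin ligase gene PUB23. CML38 was again the 1 touch gene and the 1 calmodulin-like gene that rose, or 3 and 1 when adjusted over the list alone (adjusted p = 0.210 and 0.900).

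EIN3, a transcription factor of ethylene signalling, fell at 3000 Hz by 0.50 on the log2 scale (SE 0.13), and RR16 by 0.97 (SE 0.26). LTI30 rose by 1.28 ± 0.36 as the 1 passing member of the cold (CBF) genes (3 when adjusted over the list alone, adjusted p = 0.0568) and of the cold-regulated and dehydrin genes (3 when adjusted over the list alone, median 0.75, adjusted p = 0.0410; adjusted p = 0.676 with an estimated correlation). XTH33 rose by 1.80 ± 0.46 and ATERDJ2B by 0.60 ± 0.12. The cochaperone gene Hop3 fell by 0.44 on the log2 scale (SE 0.09), NdhN, of the plastid NDH complex, by 0.59 (SE 0.17) and the glutathione transferase gene GSTU16 by 0.81 (SE 0.16). UGT84A4 fell by 0.64 (SE 0.17), or 0.387 without control replicate 3, in a list where 2 of 47 rose and 1 fell, or 1 and 1 when adjusted over the list alone (adjusted p = 0.344), and of the 14 unfolded protein response genes 1 fell besides the rise of ATERDJ2B, or 2 when adjusted over the list alone.

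The count of 1502 at 3000 Hz became 246, 254 and 476 without 3000 Hz replicates 1, 2 and 3, and 2257, 2769 and 144 without control replicates 1, 2 and 3. AT1G04770, AT1G79160 and AT2G25590 passed with any of the 6 arrays left out, the other 20 named genes did not, and the calls of rapid stress (adjusted p = 0.0675) and cold-regulated genes (highest adjusted p = 0.303) ended without control replicate 1, the latter also without 3000 Hz replicate 3. The rapid stress median of 0.59 became 0.900 without control replicate 2, and the cold-regulated median of 0.75 became 0.482 and 1.179 without control replicates 1 and 2 and 1.184 without 3000 Hz replicate 2. The plastid median of 0.23 became 0.145 without 3000 Hz replicate 3.

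Averaged over the 5 frequencies, AT2G20670 rose by 3.29 ± 0.58 on the log2 scale (9.81-fold, adjusted p = 0.0177, 15 sound arrays against 3 controls), CML38 by 2.94 ± 0.47 and AT3G62950 by 2.84 ± 0.45. EXO rose by 2.63 ± 0.52, AT2G44500 by 2.31 ± 0.43 and AT5G19120 by 2.24 ± 0.49, while AT5G60680, AT3G15450, AT2G41640 and AT3G19680 rose by 2.06 to 2.15. AT2G15020 fell by 2.31 on the log2 scale (SE 0.54) and AT1G20070 by 1.79 (SE 0.41), followed by AT2G44940, AT5G17600, AT4G26950, GIS, AT1G78170, AT4G16447, AT5G47060 and AT2G36970 with changes from -1.36 to -1.15. The sizes rest on single controls, and errors are too small wherever the controls spread widely, because the fit shares the variance over the groups. This holds for EXO and AT2G15020 but is not limited to them. Over the alternatives the average ran from 1.935 to 3.92 for EXO, from 2.524 to 4.434 for AT2G20670 and from 1.254 to 3.234 for AT5G19120. Without control replicate 1 the changes were 1.254 for AT5G19120, 1.167 for AT3G15450, -1.015 for AT1G20070, -0.831 for AT5G17600 and -0.744 for AT4G26950. Without control replicate 2 they were -3.657 for AT2G15020, -1.949 for AT4G26950 and -1.813 for AT5G47060. Without control replicate 3 they were -0.787 for AT1G78170 and -0.621 for AT2G36970. In all, 373 probe sets were higher and 467 lower, or 406 and 396 after centring each array on its median. Of the rapid stress genes 8 rose, or 14 when adjusted over the list alone, and all 27 were positive (median 0.76, camera adjusted p = 2.57e-11; adjusted p = 0.345 with an estimated correlation). At the preset correlation camera also called the touch (median 0.66, adjusted p = 0.00505) and cold (CBF) lists (median 0.56, adjusted p = 0.0147). It called the plastid-encoded (median 0.09, adjusted p = 0.00505) and cold-regulated and dehydrin lists (median 0.79, adjusted p = 0.00505) as well. Both measured cytokinin response regulators fell, ARR15 by 0.95 (SE 0.19) and RR16 by 0.88 (SE 0.20).

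At 500, 2000 and 3000 Hz together, 77 probe sets were higher and 54 lower in all 3 comparisons. Calls shared by 2000 and 3000 Hz were 145 higher and 155 lower, against 10.5 and 10.8 for independent lists, although both use the same controls and spike set. Across probe sets, the log2 changes of pairs of frequencies had a mean r of 0.608, where unchanged groups sharing these controls gave 0.741, and a mean covariance of 0.064, against 0.034 in the simulations. The pair of 500 and 1000 Hz had an r of 0.794, above its simulated 0.737, and the other 9 pairs lay below theirs in r. The covariance lay above its simulated value in all 10 pairs, by 0.013 to 0.056. The simulated noise was independent between probe sets, so shifts of many probe sets together on a control array are not allowed for.

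The average rests on which controls are used: 840 probe sets became 0 in limma without control replicate 1 (3331 at an unadjusted p under 0.05), 3177 without control replicate 2, 0 without control replicate 3 (3281 unadjusted) and 432 to 556 without any 1 sound array other than 500 Hz replicate 1 and 2000 Hz replicate 2. Within the lower spike set the average of 250, 500 and 1000 Hz gave 0 (3967 unadjusted), and 0 of the 20 named genes passed in limma in any of these 3 fits that gave 0. Fitted on the 6 arrays compared alone, limma called 1 probe set at 250 Hz and 0 at 500, 2000 and 3000 Hz, with 3698, 2586 and 3719 at an unadjusted p under 0.05, and a test without shared variance called 0 at all 5. With array weights the counts were 141 at 250 Hz, 1277 at 500 Hz and 341 for the average.

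**Figure D2:**
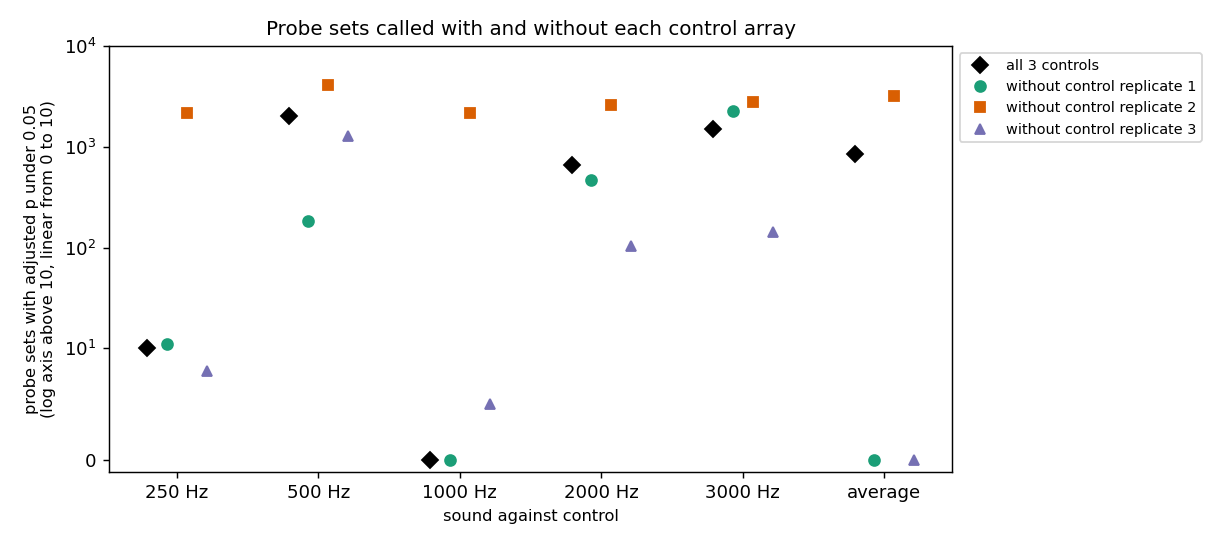
Number of probe sets with an adjusted p under 0.05 (vertical axis, logarithmic above 10 and linear below) for each frequency and the average of 5 against control (horizontal axis). Black diamonds use all 3 control arrays, and coloured points leave 1 control array out. At 1000 Hz the count was 0 with all controls and 2177 without control replicate 2.

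Among the 5 frequencies, 3556 probe sets (15.6% of those tested) differed. The photosynthetic ATP synthase gene atpA had mean log2 signals of 11.15 ± 0.42, 11.69 ± 0.05, 11.62 ± 0.10, 12.57 ± 0.07 and 12.36 ± 0.12 (SD, n = 3) from 250 to 3000 Hz, and 11.75 ± 0.18 in the controls (adjusted p = 0.00188). The autophagy gene ATG8H (AT3G06420) ran from 7.84 ± 0.26 at 500 Hz to 6.48 ± 0.04 at 3000 Hz, with 7.17 ± 0.27 in the controls (adjusted p = 0.00196). AT5G50335 was highest at 250 Hz, at 8.48 ± 0.46, and lowest at 3000 Hz, at 6.18 ± 0.21 (controls 7.44 ± 0.27, adjusted p = 0.00114). At 3000 Hz lay the highest means of AT5G63120 (6.93 ± 0.20, controls 6.14 ± 0.11), AT2G07708 (6.41 ± 0.28, controls 5.12 ± 0.05) and AT3G06980 (9.83 ± 0.07, controls 9.11 ± 0.30). These 6 genes passed with any 1 sound array left out.

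Many plastid-encoded and cytosolic ribosomal protein genes differed among the frequencies. Of 69 plastid-encoded genes 44 differed, or 54 when adjusted over the list alone (Fisher's exact test, adjusted p = 4.41e-20), and of 26 ribosomal protein genes 23, or 25 when adjusted over the list alone (exact, adjusted p = 4.00e-16), against 14% of all 13286 genes. This test takes genes as independent, while the estimated correlation within the lists was 0.448 and 0.833. These p values therefore overstate the evidence. With the spike set as a block 12 and 17 differed, against 4% of all genes. Without 3000 Hz replicates 1, 2 and 3 the ribosomal count was 7, 5 and 11. Across the spike sets, from 250 to 2000 Hz, 43 plastid-encoded genes rose (median 0.70, camera adjusted p = 1.32e-44; adjusted p = 0.591 with an estimated correlation). This count was 22 without 250 Hz replicate 1 and 28 without 2000 Hz replicate 1. Within the lower spike set their median was 0.35 from 250 to 500 Hz with 8 risen (adjusted p = 2.96e-12) and 0.45 from 250 to 1000 Hz with 3 risen (adjusted p = 3.89e-21), both with adjusted p = 0.982 with an estimated correlation. The 8 became 0, 0 and 27 without 250 Hz replicates 1, 2 and 3 and 1, 0 and 5 without 500 Hz replicates 1, 2 and 3. The 3 became 0, 0 and 30 without 250 Hz replicates 1, 2 and 3 and 1 and 0 without 1000 Hz replicates 1 and 2. From 2000 to 3000 Hz, within the higher spike set, 21 of 26 ribosomal protein genes rose (median 0.60, adjusted p = 3.82e-26; adjusted p = 0.982 with an estimated correlation). This count was 0 in limma without any 1 of these 6 arrays other than 2000 Hz replicate 2, with a median of 0.550 to 0.722 and all 26 positive over the 6 arrays left out in turn.

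Along log2 frequency 1228 probe sets rose and 1207 fell, or 1549 and 942 after centring each array on its median. Of the plastid-encoded genes 46 rose, or 53 with 1 fall when adjusted over the list alone, and of the ribosomal protein genes 6 rose, or 16 when adjusted over the list alone. With the spike set as a block 3 and 0 rose. The 6 became 2 without 250 Hz replicate 3 and 3 without any 1 of 250 Hz replicates 1 and 2, 500 Hz replicates 2 and 3, 2000 Hz replicates 1 and 2 and the 3000 Hz replicates. The calmodulin-like genes CML23, CML30 and AT1G76640 fell along log2 frequency, the 3 of 8 that did, also when adjusted over the list alone, and 0 in limma with the spike set as a block. Between 250 and 500 Hz 276 probe sets were higher and 498 lower at 500 Hz (521 and 343 after centring each array on its median), between 250 and 1000 Hz 9 higher and 46 lower at 1000 Hz, and between 2000 and 3000 Hz 532 higher and 188 lower at 3000 Hz. Between 500 and 1000 Hz limma found 0, with 2732 at an unadjusted p under 0.05.

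With the spike set as a block 1009 probe sets differed among the frequencies and 141 followed log2 frequency, and of the 6 named genes AT5G50335 and ATG8H still passed. The count of 3556 became 1972, 2031 and 2065 without 250 Hz replicate 1, 500 Hz replicate 2 and 2000 Hz replicate 1, and 1764, 1857 and 2125 without 3000 Hz replicates 1, 2 and 3. The trend count became 858 and 1536 without 250 Hz replicates 1 and 3, and 1354, 1239 and 1439 without 3000 Hz replicates 1, 2 and 3. The count between 250 and 500 Hz became 13, 71 and 1231 without 250 Hz replicates 1, 2 and 3, and 384 and 22 without 500 Hz replicates 1 and 2. Between 250 and 1000 Hz it became 5, 13 and 201 without 250 Hz replicates 1, 2 and 3, and 8, 8 and 30 without 1000 Hz replicates 1, 2 and 3. Between 2000 and 3000 Hz it became 0 in limma without 2000 Hz replicate 1 (2775 unadjusted), 13 without 2000 Hz replicate 3, 42 and 23 without 3000 Hz replicates 1 and 2, and 0 without 3000 Hz replicate 3 (2994 unadjusted). With array weights these 6 counts were 8592 among the frequencies, 4906 along log2 frequency, 3100, 1427 and 2284 for the 3 pairs with calls and 99 between 500 and 1000 Hz.

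**Figure D3:**
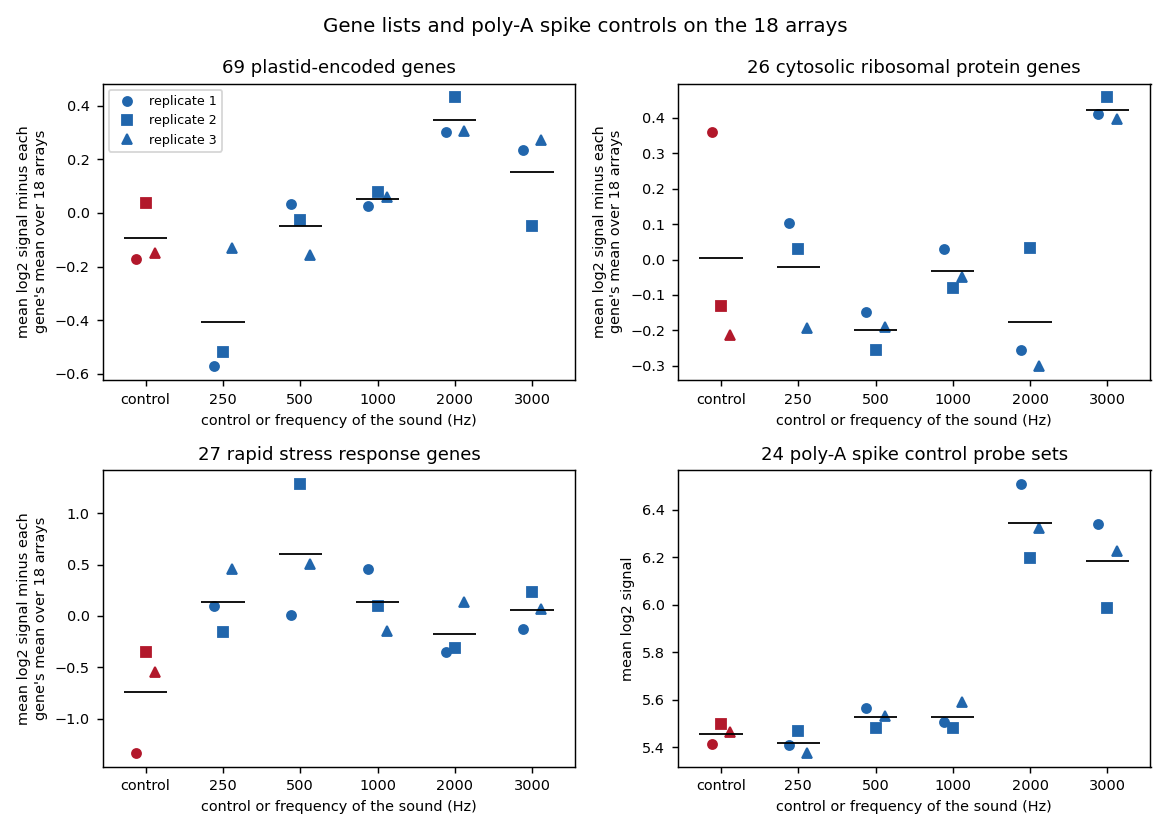
Mean log2 signal of 69 plastid-encoded, 26 cytosolic ribosomal protein and 27 rapid stress response genes, each minus the gene's mean over 18 arrays, and the mean log2 signal of 24 poly-A spike probe sets (vertical axes), by control or frequency in Hz (horizontal axes). Points are arrays, marked by replicate, with controls in red and sound in blue, and bars are group means of 3 arrays. The spike controls lie between 5.99 and 6.51 at 2000 and 3000 Hz and between 5.37 and 5.59 elsewhere.

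Of the 120 list tests, 23 were called by camera, 20 with the list higher and 3 lower, in 8 of 24 lists. Some of these lists share genes, so their calls are not independent. CML38 is in the touch, rapid stress and calmodulin-like lists, and LTI30 in the cold (CBF) and the cold-regulated and dehydrin lists. Camera with an estimated correlation and fry each called 0, with 8 and 25 at an unadjusted p under 0.05. Without control replicate 1, 14 calls were made, the 12 arrays of the lower spike set gave 15 of 72 tests, and 99 random regroupings of the 18 arrays gave a median of 12 and at most 25, or at most 34 with each array kept in its spike set. No call was made for the lists of reactive oxygen, heat shock, early auxin response, clock-associated, SWEET, pollen, root, and root and root hair genes, of which 0 members passed at any frequency in limma, nor for chaperones, of which Hop3 passed. Among the lists that are signs of other tissue, the smallest camera adjusted p was 0.846 for the root markers, 0.627 for the root and root hair markers and 0.210 for the pollen markers. Of 11 lists with 1 or 2 measured members, changes were found for EIN3 of ethylene signalling, LTI30 of abscisic acid and dehydration, and RR16 and ARR15 of the cytokinin regulators. In the other 8 lists 0 genes passed in limma at any frequency: salicylic acid defence, aliphatic and indole glucosinolates, circadian clock, photosynthesis, flavonoid synthesis, gibberellin, and dark and sugar starvation.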

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

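The tests of the control arrays, of root tissue and of the labelling sets were chosen after the results had been seen, as were the direct comparisons of pairs of frequencies and the regroupings within the spike sets, while the other regroupings and the scaling and brightness tests were fixed before their outcomes were known.

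The control arrays stood apart from each other, and for EXO and AT2G15020 control replicate 2 lay with the sound arrays. RNA quality was not separated from this: the control range of the actin 3' minus 5' signal was 0.054 times that of the 9 sound arrays of the same spike set, but the GAPDH ratio was 0.960. A wrong label on control replicate 2 stays open, since its distance from pairs of 250 Hz arrays was 0.926 times the largest distance of a 250 Hz array, while the ratio was 1.17 for 500 Hz and 1.105 for 1000 Hz, and a control would look the same if 250 Hz changed little. BSMT1 goes with the label as given, at 4.49 on control replicate 2 against 6.01 to 8.11 at 250 Hz, but it is 1 gene, named because it parts these groups. On the 100 probe sets that best set a frequency apart from the other sound groups of the lower spike set, chosen without controls, control replicate 2 lay at 0.417 for 250 Hz, -0.038 for 500 Hz and 0.603 for 1000 Hz, on a scale of 0 (other groups) to 1. The lowest array held out of the choice lay at 0.473, 0.458 and 0.639, with ranges of 0.469, 0.644 and 0.256 over the 3 held-out arrays, so none of these labels is excluded. Control replicates 1 and 3 lay at 0.539 and 0.053 for 250 Hz, 0.288 and 0.148 for 500 Hz, and 0.311 and 0.784 for 1000 Hz. Replicate 1 for 250 Hz and replicate 3 for 1000 Hz thus passed the lowest held-out array, so this scale cannot single out a wrong label. Root tissue also stays open, because 5 of 7 root genes were higher on control replicate 1 than on control replicate 2, PYK10 by 3.29, and 3 of 7 on control replicate 3, but 6 of the 7 lie among the dimmest 40% of probe sets. No biological explanation was tested.

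Plastid-encoded transcripts differed among the frequencies, with a median log2 difference of 0.703 between 2000 and 250 Hz. This list difference came from camera (adjusted p = 1.32e-44) and was not called with an estimated correlation (adjusted p = 0.591), nor was that between 1000 and 250 Hz (adjusted p = 0.982). Quantile normalization left the median at 0.703. The arrays already had like medians (6.51 to 6.63) and quartiles (4.53 to 4.65 and 8.33 to 8.41), so it could shift values little. It therefore does not decide on scaling done before the values were deposited. A labelling difference between the spike sets does not explain the part within the lower set, where 1000 Hz lay 0.450 above 250 Hz with a largest SD of the list mean of 0.241. Labelling within the lower set stays open for this part. The spike mean there was also lower at 250 Hz, 5.416 ± 0.047, than at 1000 Hz, 5.526 ± 0.058 (SD, n = 3). For the further 0.220 between 1000 and 2000 Hz, the labelling set and the sound cannot be told apart, because no array of either frequency lies in the other set. An effect of frequency itself stays among the open explanations.

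Cytosolic ribosomal protein genes lay higher at 3000 than at 2000 Hz, with a median of 0.603, and both groups belong to 1 spike set. Camera called this difference (adjusted p = 3.82e-26), but not with an estimated correlation (adjusted p = 0.982), and the 21 of 26 genes that passed became 0 in limma without any 1 of the 6 arrays other than 2000 Hz replicate 2, with all 26 still positive. Brightness is argued against, since the median exceeded those of all 10000 random lists of like brightness (percentile 100, highest random median 0.332). Quantile normalization gave 0.587, but it could shift values little on arrays that were already alike in median and quartiles. It does not decide on scaling done before. RNA quality and labelling within the set were not tested and stay open. The actin 3' minus 5' signal was 1.61 ± 0.055 at 3000 Hz and 1.75 ± 0.086 at 2000 Hz (SD, n = 3). The spike mean was 6.185 ± 0.18 at 3000 Hz and 6.343 ± 0.157 at 2000 Hz. Root tissue on the 3000 Hz arrays also stays open, with 4 of 7 root genes higher, led by PYK10 at 2.24 (adjusted p = 0.119), since most root genes are dim. Control replicate 1, with the highest PYK10 signal, also lay 0.36 above the mean for the ribosomal genes, and an effect of frequency stays untested against it.

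Differences between frequencies, tested directly, were also found for the 3556 probe sets that differed among the 5 frequencies (1009 with the spike set as a block), 774 between 250 and 500 Hz, 55 between 250 and 1000 Hz and 720 between 2000 and 3000 Hz. The rapid stress response genes differed between 2000 and 500 Hz by a median of -0.783, with 2 of 27 lower (camera adjusted p = 5.83e-06; adjusted p = 0.982 with an estimated correlation). The nuclear photosynthesis genes differed between 2000 and 250 Hz by a median of 0.233, with 3 of 21 higher (adjusted p = 6.46e-06; adjusted p = 0.591 with an estimated correlation). In both of these pairs the frequencies lie in different spike sets, so the labelling set and the frequency cannot be told apart. Within the lower set, the rapid stress genes lay on average 0.598 ± 0.644 above their means over all arrays at 500 Hz, and 0.135 ± 0.308 at 1000 Hz (SD, n = 3). The rapid stress median became -1.213 without 500 Hz replicate 1, where 7 were lower, and -0.425 without 500 Hz replicate 2. In limma 0 rapid stress genes were lower without 500 Hz replicate 2 or 3 or 2000 Hz replicate 1 or 2, and 1 was higher without 2000 Hz replicate 1. Of the nuclear photosynthesis genes 0 were higher in limma without 250 Hz replicate 1 or 2000 Hz replicate 1. Single genes that differed among the 5 frequencies were AT5G50335 (adjusted p = 0.00114), AT5G63120 (0.00140), atpA (0.00188), and ATG8H, AT2G07708 and AT3G06980 (each 0.00196). With the spike set as a block AT5G50335 and ATG8H passed (highest adjusted p = 0.0351), and the others did not (0.0542 to 0.162), so for those 4 a difference within a spike set is not shown. A signal outside the main measurement was the poly-A spike difference of 0.783 between the 6 arrays of 2000 and 3000 Hz and the 12 others, where 21 of 24 spike probe sets were higher on all 6.

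Regrouping the arrays tested whether the counts arise from any division of them. For the average, 1 of 100 regroupings of the 18 arrays (the real one) reached 840, and the highest other gave 592. These regroupings exchange arrays between the spike sets. With each array kept in its set, again 1 of 100 reached 840, and the highest other gave 453. Both kinds also mix the frequencies, so differences between frequencies add to the variance of the other groupings. They test only whether the 6 groups differ at all, and chance is not excluded for sound against silence. The count still rests on the controls, since limma gave 0 within the lower spike set (3967 unadjusted) and without control replicate 1 or 3 (3331 and 3281 unadjusted). Chance was excluded for the 3556 among the frequencies, reached in 1 of 100 regroupings of the 15 sound arrays, with a highest other of 10. The 2435 along log2 frequency were also reached in 1 of 100, with a highest other of 2. These regroupings ignore the spike sets too, and for the trend they test only whether the frequencies differ at all. With the spike set as a block and the arrays regrouped within the sets, chance was excluded for 1009 among the frequencies, reached in 1 of 100, with a highest other of 9. The 141 along log2 frequency were also reached in 1 of 100, with a highest other of 128 and the same limit for the trend. For the 23 list calls chance is not excluded: with each array kept in its set they were reached in 6 of 100 regroupings, with a highest other of 34 and a median of 12, although in 2 of 100, with a highest other of 25, when the sets were ignored. Camera with an estimated correlation and fry called 0 (8 and 25 unadjusted). For single frequencies 3 arrays against 3 give 10 splits, too few for a share under 0.05. The real and highest other counts were 2026 and 10 at 500 Hz, 657 and 64 at 2000 Hz, and 1502 and 19 at 3000 Hz, with 1 split as large each. At 250 Hz 2 splits reached the real 10, and the highest gave 296. That split sets control replicate 1 with 250 Hz replicates 1 and 2 against the others. A division other than sound thus gave a higher count, and its cause was not tested. At 1000 Hz the real count was 0, reached by all 10 splits, and the highest other 1. Between frequencies the real and highest other counts were 774 and 0 for 250 and 500 Hz, 55 and 0 for 250 and 1000 Hz, and 720 and 1 for 2000 and 3000 Hz, with 1 split as large each, and 0 and 0 for 500 and 1000 Hz, with 10.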

How the results depend on the processing

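The alternatives that separate the spike sets and the direct comparisons of frequencies were chosen after the results had been seen, while the other settings were planned. Counts of probe sets stayed within 1.5 times under quantile normalization, median centring and the fit without an intensity trend, as far as limma gave calls, and at 1000 Hz limma gave 0 in each. With dim probe sets left out, 105 probe sets differed between 250 and 1000 Hz (55 otherwise), and with robust variance 33. With replicate number as a block in the model (replicate block) this count was 26, while the counts at 250, 500, 2000 and 3000 Hz were 9, 1816, 560 and 1387. Array weights gave 141 at 250 Hz, 1277 at 500 Hz, 341 for the average, 8592 among the frequencies, 4906 for the trend, and 3100, 1427, 99 and 2284 for the pairs 250 and 500, 250 and 1000, 500 and 1000, and 2000 and 3000 Hz. The cause was not tested. The 6 arrays compared alone gave 1 at 250 Hz and 0 at 500, 1000, 2000 and 3000 Hz in limma, with 1921 to 3719 at an unadjusted p under 0.05 at the last 4. A test without shared variance gave 0 at all 5 frequencies, with 1429 to 3118 unadjusted, and has fewer degrees of freedom. The 12 arrays of the lower spike set gave 709 at 500 Hz, 0 for their average (3967 unadjusted) and 15 list calls of 72 tests. With the spike set as a block, 1009 probe sets differed among the frequencies and 141 followed the trend, a test without the differences between the sets. List calls numbered 0 with an estimated correlation and 0 with fry, with 8 and 25 unadjusted.

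Leaving out 1 array at a time, where the 2 arrays left in a group are assumed to vary like the other groups, gave counts from 3 to 2175 at 250 Hz, 2 to 4075 at 500 Hz, 0 to 2177 at 1000 Hz, 48 to 2576 at 2000 Hz and 144 to 2769 at 3000 Hz, the highest each without control replicate 2. They ran from 0 to 3177 for the average, 1764 to 3369 among the frequencies, 858 to 2644 for the trend, 13 to 1231, 5 to 201, 0 to 0 and 0 to 910 for the pairs in the order above, and 14 to 27 for list calls. The cause was not tested. The cytosolic ribosomal protein genes at 2000 Hz turned direction in camera without control replicate 1, with a median of -0.009 (adjusted p = 0.940), in a range from -0.317 over the arrays left out. The 98 tests of named genes gave 1757 values under the alternatives: 1324 kept direction and side of the threshold, 426 lost the call, 7 gained one and 0 turned direction. The mean r between frequencies was 0.621 over the brighter 60% of probe sets and 0.608 over all. A pseudocount does not apply to log2 values and was not run. Signal over background limits the 40% dimmest probe sets, which were kept in the fit.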

Other observations

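All values below were picked after the results had been seen. Several list members followed log2 frequency. The sugar transporter gene SWEET2 rose by 0.27 ± 0.07 on the log2 scale per log2 unit of frequency, and the glucosinolate gene AT2G31790 by 0.23 ± 0.05 (adjusted p = 0.00778). Among nuclear photosynthesis genes, CHLI2 of chlorophyll synthesis rose by 0.13 ± 0.03, TROL of the thylakoid by 0.09 ± 0.02 and ATPC1 of the ATP synthase by 0.06 ± 0.02. The 2 highest frequencies are also those of the higher spike set.

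Some genes varied widely over the 18 arrays with no change called at any frequency. The clock gene GI had log2 signals from 5.90 to 8.47, the anthocyanin genes DFR from 5.23 to 8.82 and UF3GT from 6.09 to 7.94, and AKINBETA1, of the SnRK1 kinase, from 8.08 to 10.58.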
